A study of Mus musculus with 8 samples.

How the data were processed

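Binding of YY1 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in C2C12, a mouse myoblast line whose cells fuse into multinucleated myotubes when serum is withdrawn. YY1 (Yin Yang 1) is a zinc-finger transcription factor that can activate or repress its targets. The series holds 8 samples: YY1 in myoblasts with 2 antibodies (SC-1703 from Santa Cruz and AB58066 from Abcam), YY1 in myotubes, control IgG in both cell states, and Ezh2, H3K4me3 and H3K27me3 in myoblasts, with 1 sample per group. Per the labels' protocols, chromatin was sonicated before immunoprecipitation and libraries were made by the Illumina paired-end procedure. Peak lists of the 2 YY1 myoblast samples were analysed. Data of the other samples were not analysed here.

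Both samples carry the same deposited file, identical byte for byte, so it was treated as 1 peak list of YY1 in myoblasts and each peak was counted once. Whether the authors called peaks on pooled reads of both antibodies, merged or intersected separate calls, or attached a list from 1 antibody to both samples is not given in the sources used here. Per the submitters' processing notes, MACS2 version 2.0.9 and genome build mm9 were used. The aligner, the control library and the q-value limit are not given in the sources used here. Each peak has a chromosome, a start, an end and the −log10 of its q-value, per the file headers. The −log10 q is a measure of significance that grows with sequencing depth as well as with enrichment, and it is neither a read count nor an occupancy. The deposited list gives no summit, fold enrichment, pileup or gene name, and the read depth behind it is unknown. In 6 rows the peak end was written with comma separators, which were removed on reading. Whether starts count from 0 or 1 is not stated, so positions are printed as the list gives them, and widths, taken as end minus start, may be 1 bp too small.

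The gene table at hand belongs to another build (GRCm38.p6) and no mm9 sequence was at hand. In all, 8 peaks lay beyond the last gene of their chromosome in that table. No position was moved between builds. The analyses planned for promoters, gene lists and the YY1 motif were therefore not run, and no peak is assigned to a gene. The comparison of myoblasts with myotubes was not made, and antibodies could not be compared. The rule for naming the 20 peaks with the highest −log10 q (ties by position) was fixed before the data were examined. All other regions and peaks given by position were chosen after the data were seen. The parts of the rule that name genes could not be applied.

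Chromosome lengths of mm9 were not at hand, and the plan was then to give counts only. The test of counts was added after the data were seen, with the end of the last peak on each chromosome standing in for its length (called its span). This overstates density where the last peak lies far from the chromosome end, by an amount that is unknown without the lengths. The count on each of 20 nuclear chromosomes was compared with its share of the summed span by an exact two-sided binomial test. Benjamini-Hochberg adjustment ran over the 20 chromosomes with a threshold of 0.05. Intervals of densities are exact 95% Poisson intervals and those of shares are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only, and peaks are not biological replicates. Peaks at or above the median −log10 q of 10.05 form the stronger set (972 peaks, 967 of them nuclear) and the others the weaker set. Shares of the stronger set were compared by Fisher's exact test, two-sided. Spacing between neighbouring nuclear peaks was compared with 1000 random placements, in which each peak kept its chromosome and width. The one-sided p counts placements with at least as many close pairs, and its smallest possible value is 0.001. Random placement is uniform along the span and takes no account of genes or of unmappable sequence. Clusters were defined as runs of at least 5 nuclear peaks with gaps under 50 kb. Differences in medians and the rank correlation were tested by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05. Like the test of counts, all the other tests with a p-value (shares of the stronger set, spacing and clusters, width against significance, peaks with a neighbour against isolated ones, and mitochondrial against nuclear peaks) were chosen after the data were seen.

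The tests of counts and spacing were run on simulated lists of 1807 peaks. In 100 simulated lists, chromosomes 11 and 15 were raised 1.6 times and chromosomes X and 1 were lowered to 0.6 times. They were recovered in that direction in 99.5% and 100% of cases. Smaller changes and changes on other chromosomes were not simulated, so their recovery is unknown. In 100 uniform lists, 0.03 chromosomes per list were called. Peaks of these lists were placed independently, whereas those of the real list lay closer together, so this rate may be too low for it. A uniform list held 10 pairs closer than 10 kb (permutation of positions with 200 placements, p = 0.806), and adding 40 pairs to it gave 50 (p = 0.00498, the smallest possible with 200). Alternatives covered the stronger set alone, neighbouring peaks counted once, another span, other distances, and lists without a block of 4 neighbouring wide peaks on chromosome 17, or without this block and the mitochondrial peaks together. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.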

Results

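YY1 binding in proliferating C2C12 myoblasts was represented by 1 list of 1820 peaks, which the samples of both antibodies shared in full. The list held 1807 peaks on the 19 autosomes and the X chromosome, and 13 on the mitochondrial genome. Peaks covered 393 kb in total. Their median width was 173.5 bp (interquartile range 128 to 260 bp), from 99 to 1855 bp. The series set out to examine YY1 targets in myoblasts against myotubes. Only the myoblast side was analysed here, without replicates, so the comparisons below are between chromosomes, regions and classes of peak within this list. All positions are in mm9.

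Most peaks were weak and a small class was very strong. The median −log10 q was 10.05, the lowest value 5.01 and the highest 513.08. Of all peaks, 598 (32.9%, interval 30.7 to 35.1%) reached 20, 309 (16.98%, 15.3 to 18.8%) reached 50, and 165 (9.07%, 7.79 to 10.5%) reached 100. At the lower end, 281 peaks (15.4%) shared the value 5.67. Values held by 10 or more peaks each accounted for 1064 peaks (58.5%), spread over 31 values. A −log10 q ranks peaks within this list and gives no level of occupancy.

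The strongest YY1 site lay on chromosome 14 at 27354300 to 27354814, with a −log10 q of 513.08. It was followed by a site on chromosome 10 at 94786525 to 94787022 (456.03). A site on chromosome 1 at 173152326 to 173152853 and another on chromosome 14 at 55236653 to 55237289 tied at 405.96. The next was on chromosome 17 at 27341427 to 27341794 (402). Chromosome 7 carried a site at 128850924 to 128851340 (388.33), chromosome 8 at 73397347 to 73397869 (382.49) and chromosome 15 at 88649589 to 88650049 (382.04). Sites on chromosome 5 at 21207426 to 21207915 and on chromosome 11 at 95171454 to 95171942 shared the value 378.61. The other 10 of the top 20 lay on chromosome 8 at 87380571 to 87381063 (370.26) and at 19784427 to 19785032 (327.19), on chromosome 2 at 31525844 to 31526597 (356.36), on chromosome 5 at 134652541 to 134652990 (347.12), on chromosome 4 at 115747488 to 115748122 (342.07) and at 70071368 to 70071864 (307.93), on chromosome 18 at 62708293 to 62708691 (342.07), on chromosome 9 at 21807122 to 21807561 (307.93), on chromosome 14 at 54980311 to 54980724 (307.93) and on chromosome 1 at 88421886 to 88422493 (289.21). The top 20 were spread over 13 chromosomes, and their widths ran from 367 to 753 bp with a median of 494 bp.

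Stronger peaks were wider. Width and −log10 q come from the same peak call, so they are not independent measures. Their relation may follow from the calling alone and need not be a property of YY1 sites. The median width was 127 bp for the 847 peaks with a −log10 q under 10, 180 bp for the 375 from 10 to 20, 233 bp for the 289 from 20 to 50, 321.5 bp for the 144 from 50 to 100, and 413 bp for the 165 at 100 and over. Across peaks, which are not independent replicates, Spearman's rho was 0.77 (permutation test, p = 1e-05, the smallest the resamples can give) and Pearson's r of the logarithms was 0.79. Among peaks below the median value rho was 0.23. The widest peaks departed from this relation. Of the 5 widest, 3 lay within 5795 bp on chromosome 17, 1 lay on the mitochondrial genome and 1 on the X chromosome at 71211390 to 71212796 (1406 bp, −log10 q 53.14).

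**Figure D1:**
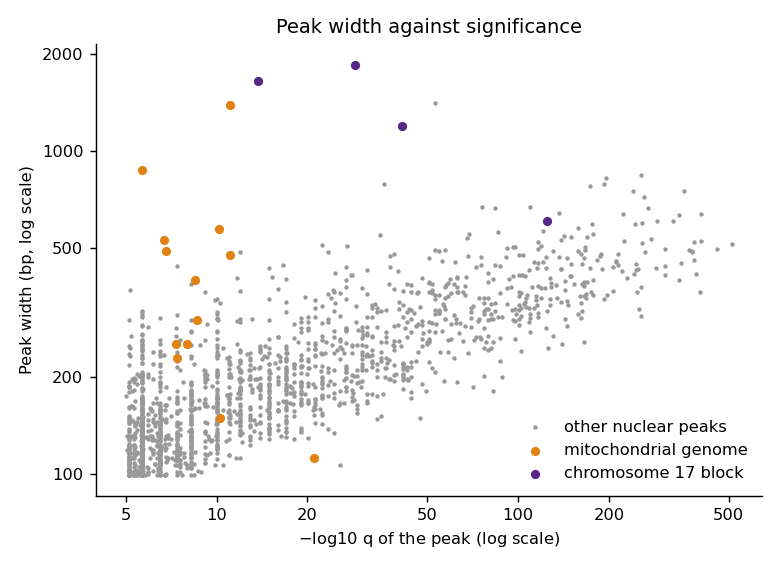
Width of each of the 1820 peaks in bp against its −log10 q, both on log axes. Each point is a peak, with the 13 mitochondrial peaks in orange and the 4 peaks of the chromosome 17 block in purple. Width rose with significance (rho 0.77), and most coloured points lie above the grey ones of similar significance.

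YY1 peaks were unevenly distributed among chromosomes. Chromosome 11, one of the most gene-dense mouse chromosomes, held the most. It had 161 peaks or 1.33 per Mb of span (95% interval 1.13 to 1.55) against 0.69 for all nuclear chromosomes. This was 1.91 times the count expected from its span (exact binomial test, adjusted p = 2.99e-13). Gene density was not measured here, and its relation to these counts was not tested. By the same exact test, chromosomes 15 (114 peaks, 1.596 times, adjusted p = 1.44e-05), 19 (64 peaks, 1.51 times, adjusted p = 0.0040), 17 (94 peaks, 1.43 times, adjusted p = 0.00282) and 10 (124 peaks, 1.38 times, adjusted p = 0.00165) were also above expectation. The X chromosome held 49 peaks, 0.42 times its expected 115.3 (exact test, adjusted p = 1.43e-11). In the exact test, chromosomes 14 (55 peaks, 0.67 times, adjusted p = 0.00391), 9 (58 peaks, 0.68 times, adjusted p = 0.00391) and 1 (97 peaks, 0.71 times, adjusted p = 0.00151) were below. Thus 5 chromosomes lay above and 4 below expectation by the binomial test, and 11 did not pass it. Among peaks at or above the median −log10 q alone, 6 of these 9 chromosomes passed, and chromosomes 9 (0.85 times, exact test, adjusted p = 0.483), 10 (0.96 times, adjusted p = 0.868) and 15 (1.31 times, adjusted p = 0.143) did not. With all peaks, chromosome 17 no longer passed when peaks closer than 100 kb were counted once (1.15 times, exact test, adjusted p = 0.445). Chromosome 12 lay near the threshold (0.75 times, exact test, adjusted p = 0.0554), so its side may depend on the span standing in for its length.

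**Figure D2:**
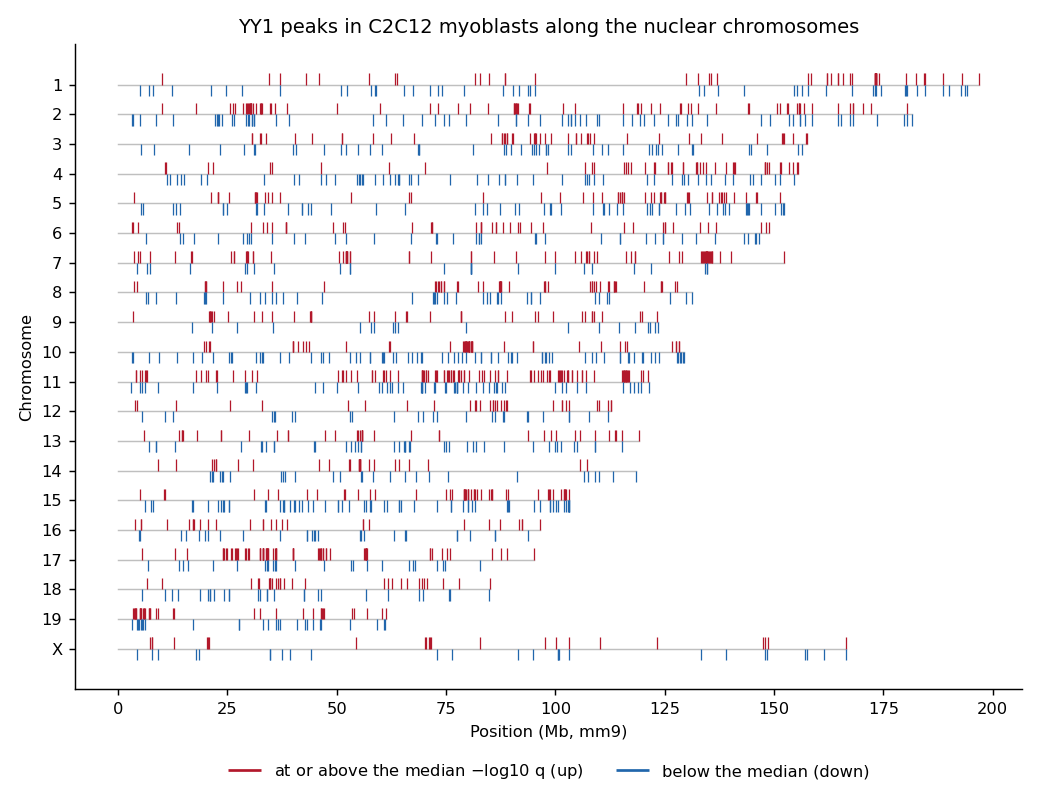
Position of each nuclear peak in Mb along the 20 chromosomes. Red ticks above the line are peaks at or above the median −log10 q of 10.05 and blue ticks below it are the weaker peaks. Chromosome 11 carries 161 ticks and the X chromosome 49.

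Chromosomes also differed in the strength of their peaks. Of all nuclear peaks, 53.5% belonged to the stronger set, at or above a −log10 q of 10.05. The share was 74.2% on chromosome 7 (72 of 97, interval 64.3 to 82.6%, Fisher's exact test, adjusted p = 0.000454), 73.4% on chromosome 17 (69 of 94, adjusted p = 0.000704) and 64.6% on chromosome 11 (104 of 161, adjusted p = 0.0183). It was 37.1% on chromosome 10 (46 of 124, interval 28.6 to 46.2%, Fisher's exact test, adjusted p = 0.00115). The other 16 chromosomes did not pass this test. With a limit of 20 in place of the median, chromosomes 7 (51.5%, Fisher's exact test, adjusted p = 0.00269) and 17 (46.8%, adjusted p = 0.0469) passed against 33.0% of all nuclear peaks, while chromosomes 10 (26.6%, adjusted p = 0.329) and 11 (41.6%, adjusted p = 0.0964) did not. With a limit of 50, the share was 30.9% on chromosome 7 (30 of 97) against 17.1% of all nuclear peaks (Fisher's exact test, adjusted p = 0.0143). With that limit the share was 7.02% on chromosome 15 (8 of 114, Fisher's exact test, adjusted p = 0.0188), and chromosomes 10, 11 and 17 did not pass. Fisher's test treats peaks as independent, although peaks with a neighbour were stronger than isolated ones (below). These p-values may therefore be too small.

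Stronger and weaker peaks were then counted separately against the same spans. In the stronger set, chromosome 11 held 2.31 times its expected count (exact binomial test, adjusted p = 1.67e-13), chromosome 17 1.96 times (adjusted p = 1.88e-06) and chromosome 19 1.67 times (adjusted p = 0.0109), while chromosomes 9, 10 and 15 did not pass, as given above. In the weaker set, chromosomes 15 and 10 held 1.93 and 1.87 times their expected counts (exact test, adjusted p = 1.24e-05 and 3.52e-06), chromosome 11 held 1.46 times (adjusted p = 0.0174), and chromosome 17 0.82 times (adjusted p = 0.475). Chromosomes 7 and 9 held 0.51 and 0.48 times their expected weaker peaks (exact test, adjusted p = 0.000808 and 0.00128). The X chromosome was low in both sets, at 0.37 times for stronger and 0.49 times for weaker peaks (exact test, adjusted p = 1.15e-07 and 0.000186).

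**Figure D3:**
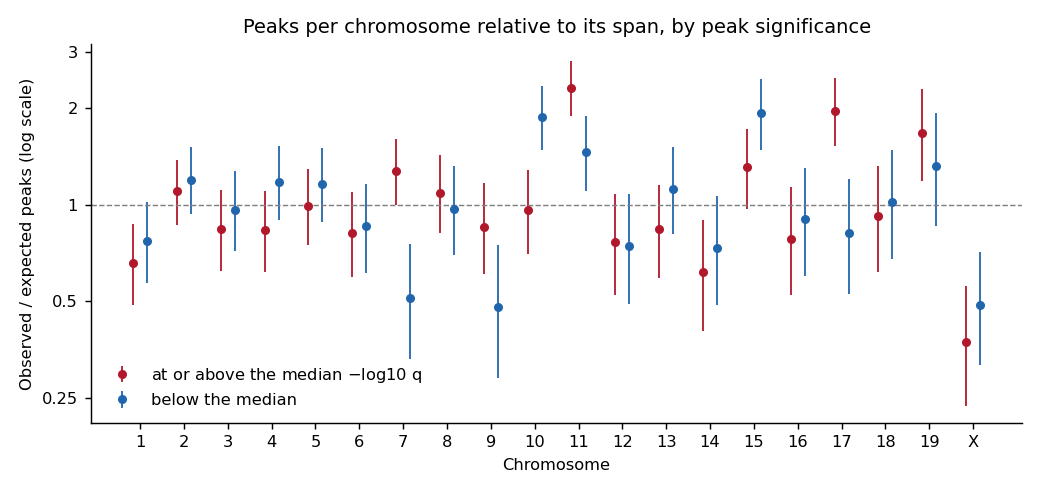
Observed over expected number of peaks per chromosome, on a log axis, for peaks at or above the median −log10 q (red) and below it (blue). Points are ratios, bars are exact 95% Poisson intervals and the dashed line marks 1. Chromosomes 11, 17 and 19 are high in red and chromosomes 10 and 15 in blue, and the X chromosome is low in both.

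Nuclear YY1 peaks lay closer together than random placement gave. Placement was uniform along the span, without regard to genes or unmappable sequence, so the excess need not be particular to YY1. The median gap between nuclear neighbours was 547 kb. In all, 69 neighbouring pairs were closer than 10 kb against 14.2 in random placements (highest of 1000, 29), a 4.85-fold excess (permutation of positions, p = 0.001, the smallest possible). At 100 kb there were 327 pairs against 133.5 (highest 167), a 2.45-fold excess with the same p. Counting peaks closer than 1 kb once lowered the excess of pairs closer than 10 kb to 2.37-fold (permutation of positions, p = 0.001), since 37 of the 69 pairs were closer than 1 kb. Within the stronger set, pairs closer than 100 kb were 4.22 times as frequent as in random placements (174 against 41.2, permutation of positions, p = 0.001), and within the weaker set 1.604 times (48 against 29.9, p = 0.0030).

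Peaks with a neighbour were stronger than isolated ones. The 555 nuclear peaks with another peak closer than 100 kb had a median −log10 q of 15.93 (interquartile range 7.57 to 42.7), and the 1252 without had 8.69 (5.67 to 24.8). The difference in medians was 7.25 (permutation test, p = 1e-05, the smallest possible). Permuting labels within chromosomes 10000 times gave the smallest possible p as well (1e-04). Both permutations treat peaks as independent, although peaks with a neighbour come in runs, so these p-values may be too small. Of the peaks with a neighbour 66.8% belonged to the stronger set, and of the isolated ones 47.6%.

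Among nuclear peaks, to which the windows and clusters below were limited, the densest region was on chromosome 1 between 172555653 and 173341572. There 14 peaks fell within 1 Mb, 11 of them in the stronger set. In 1000 random placements the densest 1 Mb window held a median of 6 and at most 10 peaks. Windows with 12 peaks lay on chromosome 7 at 133726881 to 134655925 and on chromosome 17 at 33102653 to 34093098. Among windows that do not overlap these, those with 11 peaks lay on chromosome 7 at 52104230 to 53086376, on chromosome 10 at 79316783 to 80289495 and on chromosome 19 at 5088475 to 6077276. On chromosome 10, where 37.1% of all peaks belonged to the stronger set, 10 of the 11 peaks of that window did. By the cluster rule (at least 5 nuclear peaks with gaps under 50 kb) there were 4 clusters with 27 peaks in all. Random placements gave 0.006 clusters on average (at most 1 in a placement, permutation of positions, p = 0.001). On chromosome 1, 8 peaks spanned 124 kb from 173152326 to 173275906, with a median −log10 q of 76.9 and a highest value of 405.96. On chromosome 7, 8 peaks spanned 136 kb from 134519487 to 134655925 (median 65.7) and 6 peaks spanned 94.2 kb from 80669355 to 80763592 (median 8.24). On chromosome 17, 5 peaks spanned 89.0 kb from 56723863 to 56812851 (median 16.96). Among these 5 was a pair closer than 1 kb. With that pair counted once, the run would fall short of the cluster rule. The clusters of 8 peaks on chromosomes 1 and 7 each held such a pair as well, but would still meet the rule. The windows, the number of clusters and its p were not recalculated with peaks closer than 1 kb counted once.

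Peaks on the mitochondrial genome and in a block on chromosome 17 had a different shape from the rest. Whether these peaks mark YY1 binding or background was not tested, and the IgG samples were not analysed. The 13 mitochondrial peaks covered 6021 bp, or 37.4% of the stretch from the first to the last of them, whereas nuclear peaks covered 0.0148% of their span. Their median width was 397 bp against 173 bp for nuclear peaks (permutation test, p = 4.00e-05). Their median −log10 q of 8.47 was not distinguishable from the nuclear median of 10.06 (permutation test, p = 0.744). Both permutations treat peaks as independent, although the mitochondrial peaks are neighbours on the same small genome, so the p for width may be too small. The highest mitochondrial −log10 q, 20.98, belonged to the narrowest mitochondrial peak, at 16064 to 16176. The chromosome 17 block consisted of 4 peaks from 39979961 to 39985756 that covered 91.7% of 5795 bp. Their widths were 1855, 608, 1198 and 1653 bp and their −log10 q values 28.8, 125, 41.18 and 13.69.

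**Figure D4:**
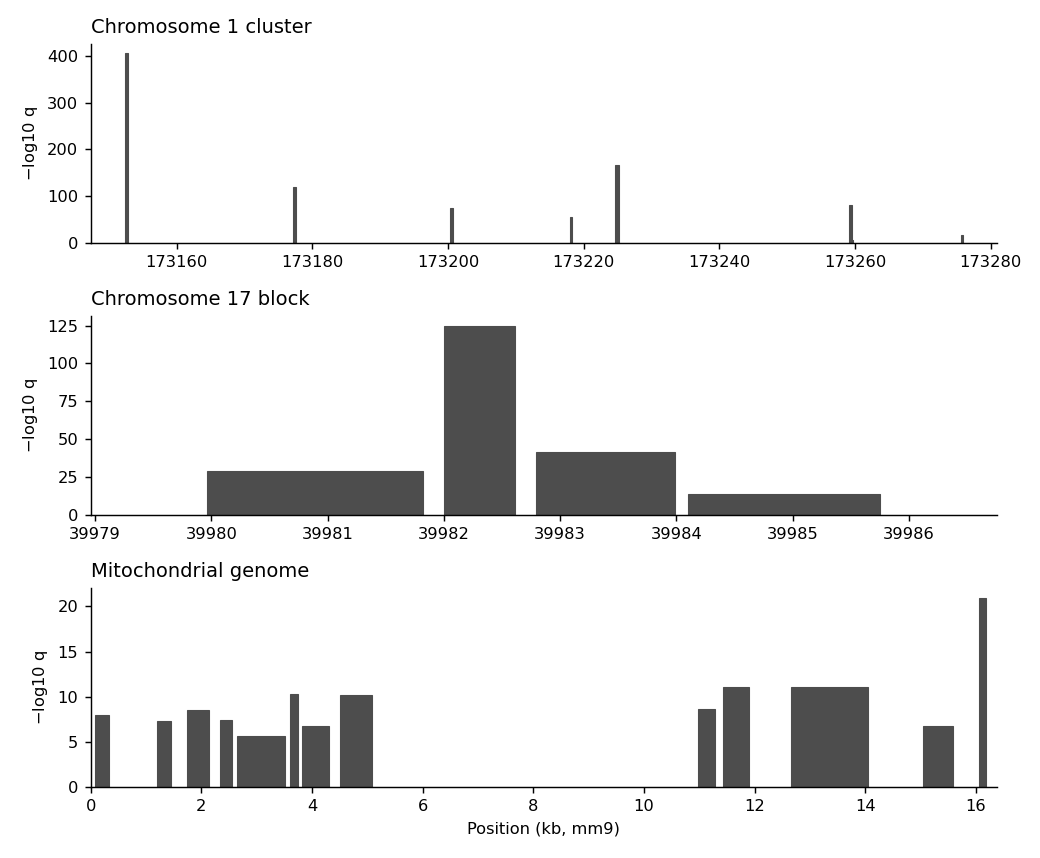
Peaks drawn to scale along the chromosome 1 cluster, the chromosome 17 block and the mitochondrial genome (positions in kb). Each bar spans a peak from start to end and its height is the −log10 q, on an axis that starts at 0. The 8 peaks of the chromosome 1 cluster cover 2906 bp of 124 kb, while the 4 peaks of the block cover 91.7% of its length.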

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

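Of the alternatives below, the stricter overlap, the stronger set for the number of peaks, their sharing and the counts per chromosome, and the count of peaks closer than 10 kb as 1 were chosen before the data were examined, and all others afterwards. Of 74 alternative values, 11 had an outcome fixed by the setting and say nothing about stability: the number of peaks in the stronger set, the 2 overlaps of a list with its own copy, and the counts on 8 other chromosomes without the chromosome 17 block. Of the other 63, 54 kept their direction and their side of the threshold (counts within 1.5 times). Keeping only peaks at or above the median value left 972 of 1820 peaks, shared in full because the lists are identical. On that set, chromosome 10 changed from 1.38 to 0.96 times its expected count (exact binomial test, adjusted p = 0.868), and chromosomes 15 (1.31 times, adjusted p = 0.143) and 9 (0.85 times, adjusted p = 0.483) no longer passed, with fewer peaks tested. The number of chromosomes that departed from expectation was 9 and ranged from 6 to 10 over the alternatives. The excess of close pairs ranged from 2.37 to 7.92 and passed in each of its alternatives, all chosen afterwards. The lower share of stronger peaks on chromosome 10 and the higher one on chromosome 11 did not pass with limits of 20 or 50, nor did that on chromosome 17 with 50, while that on chromosome 15 passed there and not at the median. Without its block, chromosome 17 still passed (1.37 times, exact test, adjusted p = 0.00835), but it did not with all peaks when those closer than 100 kb were counted once (1.15 times, adjusted p = 0.445). No paired analysis was possible because each group had 1 sample, and no replicate could be left out. Planned analyses of promoters, gene lists and motifs and their alternatives were not run, for want of mm9 sequence and annotation. Read depth is unknown, so absent peaks cannot be read as absent binding.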

Other observations

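All tests in this part were chosen after the results were seen.

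Weak peaks made up the excess of YY1 peaks on chromosome 10 and most of that on chromosome 15. Together these chromosomes held 1.90 times their expected number of peaks below the median −log10 q (142 of 840, 95% interval 1.62 to 2.20), 1.11 times those at or above it (96 of 967, interval 0.91 to 1.35) and 0.94 times those at or above 50 (26 of 309, interval 0.63 to 1.36). Chromosome 15 alone held 64 weaker peaks against 33.2 expected and 50 stronger ones against 38.2. Chromosome 10 alone held 78 weaker peaks against 41.7 expected and 46 stronger ones against 47.9. The pooled ratios hide a difference in the strongest peaks. Of the 26 at or above 50, 18 lay on chromosome 10 (14.5% of its peaks) and 8 on chromosome 15 (7.02%). Chromosomes 11 and 19 held 1.41 times their expected weaker peaks (interval 1.13 to 1.73) and 2.03 times their expected peaks at or above 50 (interval 1.504 to 2.66). A few dense clusters do not account for the excess of all peaks on chromosomes 10 and 15, since counting peaks closer than 100 kb once left 1.47 times the expected number (interval 1.28 to 1.68). The weaker peaks alone were not recounted in this way. More DNA from these chromosomes in the library, such as extra copies in the line, may lift background over the calling limit. The values here do not settle this, since more DNA could raise reads at bound sites as well. An excess of stronger peaks would therefore not speak against it. The same account was not examined for other chromosomes. Weaker peaks exceeded expectation in 10 of 11 bins of 20 Mb (end bins under 10 Mb left out), and stronger peaks in 4. On chromosome 15 the stronger ratios were the higher ones at 60 to 80 Mb (1.75 against 1.55) and at 80 to 100 Mb (2.29 against 1.86). Peaks of both sets were also dense in the left-out end of chromosome 15, beyond 100 Mb, which these counts do not show. The contrast between weak and strong peaks is also how the pattern was noticed. The myotube, IgG, Ezh2 and histone samples, which could bear on it, were not analysed here, and no biological explanation was tested.

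Each of the 13 mitochondrial peaks was ranked by width among nuclear peaks within 10% of its own −log10 q. The median of these 13 percentiles was 99.4, and 11 of them lay above 90. The narrow peak at 16064 to 16176, with the highest mitochondrial value of 20.98, lay at percentile 0. This describes the widths given above and tests no explanation of them.

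The chromosome 17 block, with 4 peaks over 91.7% of 5795 bp, and the 1406 bp peak on the X chromosome are further stretches where width was large for the significance.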
